A study of Rattus with 18 samples.

How the data were processed

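RNA from 18 samples of infarcted left ventricular free wall of Sprague-Dawley rats was measured by NanoString hybridization, a method that counts barcoded probes without amplification. Per the labels' protocols, the infarction lasted 35 min, and 50 to 100 ng of RNA was hybridized per sample. The agent and time point labels give 4 groups: control at day 1 (n = 4), iECM at day 1 (n = 5), control at day 3 (n = 4) and iECM at day 3 (n = 5). iECM is an infusible extracellular matrix. The labels conflict over treatment: the treatment text of all 18 samples states an infusion of iECM, while the agent label of 8 of them is control. The groups follow the agent label, each value of iECM against control rests on it, and what the control hearts received is not stated. The labels do not state that each sample is a separate animal, so p-values measure the spread between these samples, each of which is called a heart. Replicate numbers follow accession order and pair nothing.

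The deposited value table holds whole-number counts for 394 numbered rows, read as raw counts because the totals differ between samples. It does not pair the rows with gene names, so no row was named. Rows 375 to 380 were read as 6 positive-control probes and rows 381 to 388 as 8 negative-control probes. This reading was made from the values, after they were seen. The 6 rows form a ladder of mean counts from 47449 down to 68, their lowest pairwise correlation over samples is 0.880 on the log2 scale, and the other 8 rows stay between 2 and 31 counts. The other 380 rows were taken as gene probes. Gene counts per sample ranged from 816397 to 1687688, and 41 gene probes were at or below the mean plus 2 SD of the negative-control rows in each of the 18 samples. Of 153 sample pairs none was identical, and the smallest chi-square per degree of freedom was 7.24.

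The authors' deposited tables list 11 genes for day 1 and 23 for day 3, each with a log fold change, an lr score, a p-value and a q-value, per the file headers. The tool is not given in the sources used here. The headers state neither the base nor the direction of the fold change. Both were inferred from the counts, by pairing the deposited fold changes and lr scores with those of the unnamed rows under 4 readings. The mean distance was smallest for log2 of iECM over control, at 0.0602 for day 1 and 0.0420 for day 3, against at least 0.185 and 0.218 for the other readings. The median gap in fold change alone barely separates the directions at day 1, at 0.0103 for log2 of iECM over control and 0.0126 for the reverse, against 0.0150 and 0.0434 at day 3. On that measure the direction at day 1 stays unsure. The deposited log2 fold changes are printed on that reading, and the pairing was not used to name any row. The q-values correspond to 374 genes tested on each day. The authors also deposited a KEGG table of 38 pathways and a gene ontology table of 707 biological process terms for the day 3 genes, with p-values and the number of genes per term, a count of another kind. Their p-values were recomputed as hypergeometric tails, and the ratio to the deposited p-values was 1 for all terms. The 15 Entrez identifiers of the KEGG table were all matched to symbols through NCBI RefSeq's gene table (GRCr8).

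The design fixed before the data were examined assumed normalized values and limma. Since the table holds counts, edgeR 4.0.16 was used: filterByExpr with a minimum count of 10, which kept 371 of 380 probes, TMM scaling (levels are given as CPM, counts scaled to the library size), and the quasi-likelihood test on 1 model of 4 group means with 14 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Fold changes are given with a standard error (SE) and 95% intervals. The 5 contrasts were iECM against control on each day, their difference, and day 3 against day 1 in each agent. All 26 gene lists fixed beforehand could not be tested on unnamed rows, so they serve only to group the genes that the authors' tables name. The rule for named genes, fixed beforehand, took each gene of those tables, and all 34 are given. For the time comparisons the rule asked for 10 rising and 10 falling genes. Because rows carry no names, only the 2 rows with the largest rise and the 2 with the largest fall in control hearts are given.

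The test was checked on counts simulated for the day 3 comparison from the real means, library sizes and dispersions of 371 probes. With 20 probes changed, it recovered 32.5% of 1.5-fold, 80% of 2-fold and 95.5% of 3-fold changes, and 4.88% of its calls were false. With 200 changed, it recovered 61.5% of 1.5-fold and 88% of 2-fold changes. With none changed, 0.0479 of unadjusted p-values were under 0.05. Each probe was drawn independently, whereas in the real hearts 1 axis held 39.4% of the variance within groups. The simulated rates leave out such shared variation and may not hold for these hearts.

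Alternatives included DESeq2 1.42.0, limma 3.58.1 on log2 counts with pseudocounts of 0.5, 1 and 10, other scalings, filters and variance models, sample weights, and each sample left out in turn. Others were chosen after seeing the data, some with their counts already seen: an edgeR likelihood ratio test, a likelihood ratio model with a background term, positive-control scaling, a covariate for the leading axis of variation within groups, a background filter, the 2 samples farthest out on that axis left out, and unscaled limma. The background model took rows 389 to 394 as reference probes, an assumption from their place in the table. It scaled each sample on them and on the positive-control rows. Scaling on named housekeeping genes and the list tests were not run, since they need gene names. R 4.3.3, Python 3.11.15 and scipy 1.17.1 were used.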

Results

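Gene expression was measured in 18 samples of infarcted rat left ventricular free wall, labelled day 1 or day 3, to examine how an infusible extracellular matrix (iECM) acts on inflammatory, fibrotic and metabolic pathways. Control hearts numbered 4 on each day and iECM hearts 5. The summed gene count was 953364 ± 192466 counts in day 1 control hearts (SD, n = 4) and 1076812 ± 211962 counts in day 1 iECM hearts (SD, n = 5). It was 1479306 ± 271954 counts in day 3 control hearts (SD, n = 4) and 1417928 ± 229204 counts in day 3 iECM hearts (SD, n = 5). The first principal component held 60.6% of the variance and separated the days. Day 1 hearts lay between -8.57 and -5.87 on it and day 3 hearts between 2.39 and 9.98, with both agents present on each side.

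**Figure D1:**
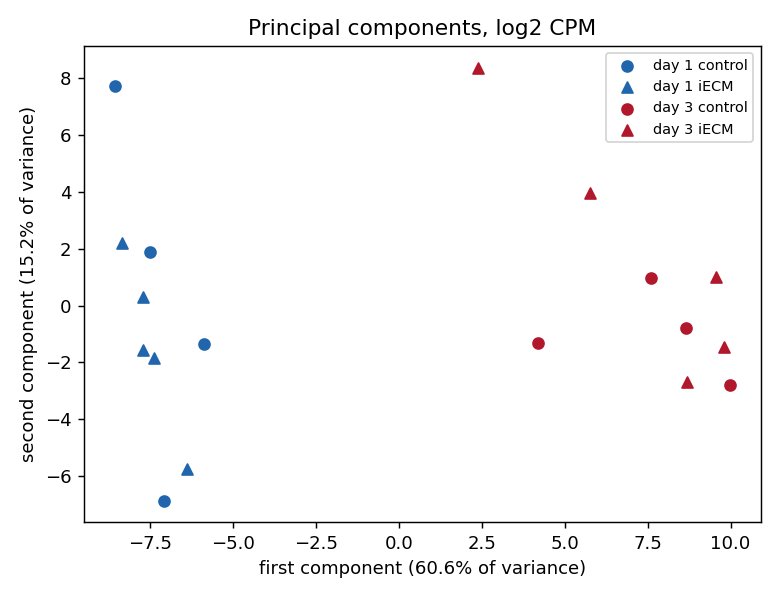
Each point is 1 heart, placed by its scores on the first (60.6% of variance) and second (15.2%) principal components of log2 CPM, with colour for day and shape for agent. Days separate along the horizontal axis, and control and iECM hearts overlap within each day.

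The first comparison asked which genes differed between iECM and control hearts at day 1. Acta2, the smooth muscle actin of contractile vessel cells and activated fibroblasts, was lower with iECM in the authors' deposited table, with a log2 fold change of -0.61 and q = 0.0314. The direction of these tables is inferred from the counts, not stated in them, and on the median gap in fold change it is unsure at day 1. Acta2 was the single gene of the 11 listed for day 1 with a q under 0.05. Of the endothelium and angiogenesis list, the authors' deposited table held Vegfa, an endothelial growth factor, at 0.25, Fgf2, a fibroblast growth factor, at 0.36, and Nrp1, a co-receptor for vascular endothelial growth factor, at -0.27. The largest values in the authors' deposited table were those of Il23a, a subunit of the cytokine interleukin-23, at 1.82, and Nrg1, a growth factor that signals to cardiomyocytes, at 1.79.

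Bmp7, a ligand of the TGF-beta family, stood at 0.83 in the authors' deposited table, and the remaining genes were Amot at 0.88, Mapk11 at 0.69, Acvrl1 at -0.29 and Fmn1 at -0.85. These 10 genes other than Acta2 had q = 0.989 in the authors' deposited table. With no change, 18.7 of 374 genes are expected at an unadjusted p under 0.05 if the p-values are exact, more than the 11 listed, and the authors' test is not given. From the deposited counts, edgeR's quasi-likelihood test called 0 of 371 unnamed probes, and 3 had an unadjusted p under 0.05. DESeq2 and limma also called 0. The 3 probes were all lower with iECM, while the authors' deposited table held 7 genes higher and 4 lower on the inferred direction. The 95% interval of 341 probes lay inside a 2-fold change in either direction, and that of the other 30 did not exclude one. Of the 341 probes, 21 were at or below background in each of the 18 samples, where a fold says little about a gene.

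The same question was asked at day 3. The authors' deposited tables for the 2 days shared 0 genes, where lists of these sizes drawn at random from 374 genes would share 0.676 on average, so this does not show a difference between the days. Nos2, the inducible nitric oxide synthase of activated macrophages, was lower with iECM, with a log2 fold change of -0.99 and q = 0.0437 in the authors' deposited table. Cpt1a, which carries long-chain fatty acids into mitochondria, was higher, at 0.52 with q = 0.0437 in the authors' deposited table. Those were the 2 genes of 23 with a q under 0.05.

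Of the pro-inflammatory cytokine and chemokine list, which holds 29 genes, 5 were in the authors' deposited table for day 3 and all 5 had negative values. Besides Nos2 they were Il6 at -0.79, Cxcl10 at -0.56, Cxcl1 at -0.47 and Il1b at -0.38, with q-values from 0.182 to 0.646 in the authors' deposited table. The largest unadjusted p listed there was 0.0486, so only genes of small p are seen. Which other list members were measured is not known, and these 5 do not show how the list moved. Cxcl10, a chemokine induced by interferon, also belongs to the interferon response list. Of the fatty acid metabolism list, the authors' deposited table held Cpt1a and Cd36, a fatty acid transporter, at 0.45 with q = 0.615. Slc2a1, the glucose transporter GLUT1, stood at -0.39 with q = 0.646 in that deposited table of the authors. Mmp8, the neutrophil collagenase, at 1.09, and Timp3, an inhibitor of matrix proteases, at 0.40, were the members of the protease list in the authors' deposited table.

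Foxp3, the transcription factor of regulatory T cells, had a value of 1.04 and q = 0.408 in the authors' deposited table. Sln, a regulator of the sarcoplasmic calcium pump, at 1.96, and Myl4, the atrial essential myosin light chain, at 1.87, had the largest values in the authors' deposited table that can be read as a size. S100b at 1.16, Crhr2 at 0.70, Prx at 0.37, Lrg1 at 0.34, Smad6 at 0.30, Lifr at 0.30 and Pdgfb at 0.20 were also positive there. Junb, a transcription factor subunit, and Thbs1, a matrix glycoprotein, both stood at -0.34 in the authors' deposited table. Rnase1 was listed at 25.9 in the authors' deposited table, which is not a size that counts can hold, since the highest count in the value table has a log2 of 18.0.

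**Figure D2:**
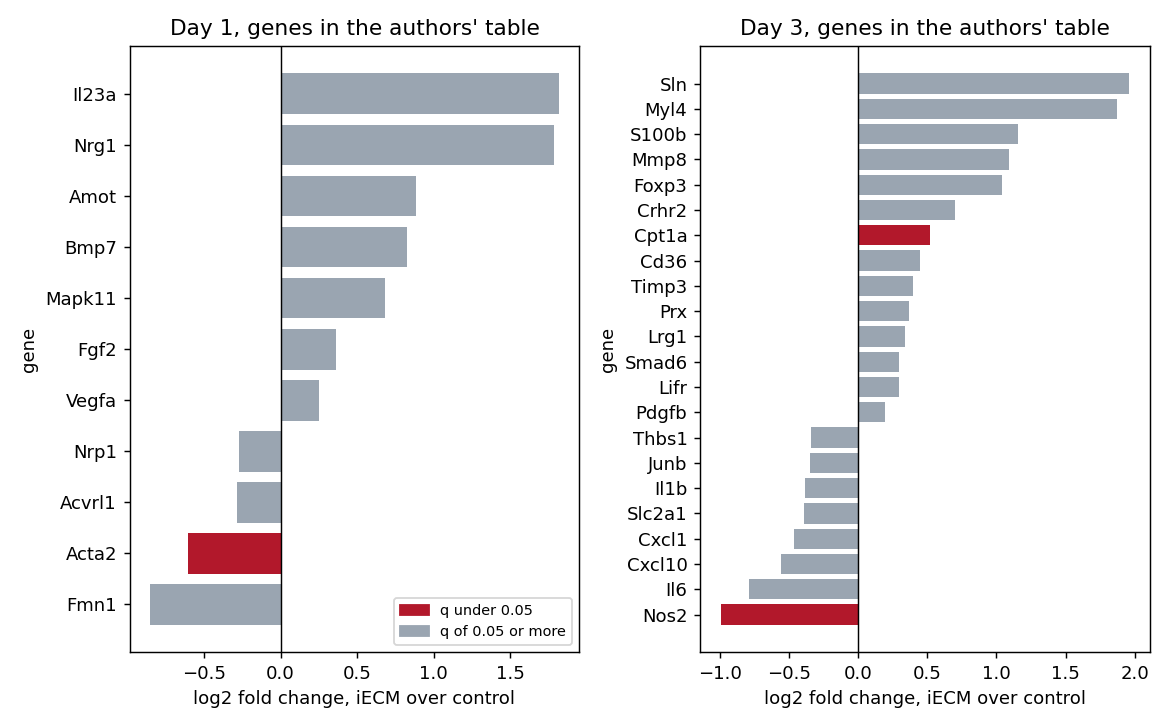
Bars give the log2 fold change of iECM over control in the authors' deposited tables for day 1 (11 genes) and day 3 (22 genes). Rnase1 was left out at 25.9, and no error is drawn since the tables give none. Base and direction were inferred from the counts, and the direction at day 1 is unsure on the median gap in fold change. Red bars have a q under 0.05, which are Acta2 at day 1 and Cpt1a and Nos2 at day 3.

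With no change, the same 18.7 of 374 genes are expected if the p-values are exact, fewer than the 23 in the authors' deposited table, and the authors' test is not given. A likelihood ratio model with a background term was run here as an alternative, and whether the authors used such a model is not known. On counts simulated with no change at day 3 it gave 0.101 of p-values under 0.05 rather than 0.05. On the deposited counts it gave 32 of 374 at day 3 and 10 of 374 at day 1. These shares may not apply to the authors' p-values. From the deposited counts, edgeR's quasi-likelihood test called 0 of 371 unnamed probes at day 3, and 11 had an unadjusted p under 0.05. DESeq2, limma and edgeR's likelihood ratio test also called 0. The likelihood ratio model with a background term called 2, both higher with iECM, whereas Nos2 was lower and Cpt1a higher in the authors' deposited table. Of the 11 probes, 3 were higher and 8 lower with iECM. The authors' deposited table held 15 genes higher and 8 lower on the inferred direction. The 95% interval of 339 probes lay inside a 2-fold change, 24 of them at or below background in each of the 18 samples.

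The authors' deposited KEGG table for the 23 day 3 genes was led by the TNF signaling pathway, with Cxcl1, Cxcl10, Il1b, Il6 and Junb, at an adjusted p of 1.49e-04. The IL-17 signaling pathway held Cxcl1, Cxcl10, Il1b and Il6, at an adjusted p of 7.55e-04 in the authors' deposited table. Insulin resistance held Cd36, Cpt1a, Il6 and Slc2a1, at an adjusted p of 9.23e-04 in the authors' deposited table. The adipocytokine signaling pathway held Cd36, Cpt1a and Slc2a1, at an adjusted p of 0.00298 in the authors' deposited table. The authors' deposited table used 9373 background genes, more than the 374 that could have been listed. Its test used the 17 day 3 genes that had a KEGG annotation. Of all 23 day 3 genes, 21 had a q of 0.05 or more.

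Whether the effect of iECM differed between the days was tested as an interaction. No named gene can be given, because the authors' deposited tables hold no such contrast. edgeR's quasi-likelihood test called 0 of 371 unnamed probes, 10 had an unadjusted p under 0.05, and DESeq2 and limma also called 0. The 95% interval of 269 probes lay inside a 2-fold difference between the days, 8 of them at or below background in each of the 18 samples. Across probes, which are not independent replicates, the effects on the 2 days had a Pearson correlation of -0.123 and a Spearman correlation of -0.259, with the same sign in 137 of 371 probes. Without day 1 control replicate 1 the Pearson correlation was 0.359.

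The change from day 1 to day 3 was then examined within each agent. In control hearts 169 of 371 probes changed by edgeR's quasi-likelihood test, of which 93 rose and 76 fell. The probe in row 147 rose by 3.47 on the log2 scale (SE 0.25, edgeR adjusted p = 5.22e-08), from 608 ± 173 to 6757 ± 673 CPM (SD, n = 4 each). Row 93 rose by 3.45 (SE 0.28, edgeR adjusted p = 1.08e-07). Row 310 fell by 2.46 (SE 0.32, edgeR adjusted p = 2.75e-05), from 15817 ± 6782 to 2876 ± 365 CPM (SD, n = 4 each). Row 273 fell by 2.16 (SE 0.52, edgeR adjusted p = 0.00454), and by 1.22 without day 1 control replicate 2. The files do not pair these rows with gene names.

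In iECM hearts 154 of 371 probes changed by the same edgeR test, of which 72 rose and 82 fell. Row 147 rose by 3.00 (SE 0.22, edgeR adjusted p = 2.59e-08), row 93 rose by 3.53 (SE 0.25, edgeR adjusted p = 1.97e-08), row 310 fell by 3.30 (SE 0.29, edgeR adjusted p = 2.45e-07), and row 273 fell by 2.71 (SE 0.47, edgeR adjusted p = 2.11e-04). The interaction was not called for any of these 4 rows, with edgeR adjusted p-values from 0.928 to 0.955. Both agents shared 68 rising probes, against 18.0 for independent lists, and 51 falling probes, against 16.8. No probe was called in opposite directions, and the fold changes had a Pearson correlation of 0.929 across probes.

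**Figure D3:**
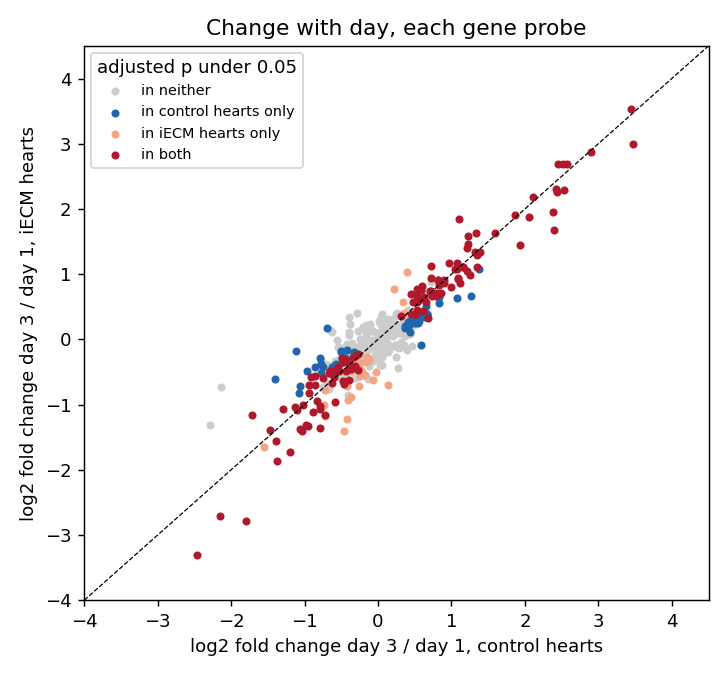
Each point is 1 of 371 gene probes, with its log2 fold change from day 1 to day 3 in control hearts on the horizontal axis and in iECM hearts on the vertical axis, coloured by where its adjusted p was under 0.05. Points lie along the dashed line of equal change (Pearson correlation 0.929).

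The balance of rising and falling probes depends on the scaling. With samples scaled on the positive-control rows, the median of all probes moved by 1.10 in control hearts and 1.02 in iECM hearts, and 249 probes rose and 2 fell in control hearts, against 259 and 3 in iECM hearts. With samples shifted to 1 median, the median of all probes stood at -0.24 in both agents, 69 rose and 111 fell in control hearts, and 62 rose and 116 fell in iECM hearts. With quantile normalization 70 rose and 86 fell in control hearts. Rows 147, 93, 310 and 273 had the same directions under these scalings, and their sizes moved. With positive-control scaling row 310 fell by 1.34 and row 273 fell by 1.10 in control hearts, while row 147 rose by 4.61 and row 93 rose by 4.62. In iECM hearts the same scaling gave -2.21 for row 310, -1.69 for row 273, 4.15 for row 147 and 4.69 for row 93.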

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

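The tests of the positive-control rows were chosen only after that difference was seen, and so were the likelihood ratio model with a background term and edgeR's likelihood ratio test.

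A signal outside the gene probes differed between the days. The sum of the 6 rows read as positive controls, probes that in such panels detect added RNA rather than tissue RNA, was 75474 ± 6469 counts at day 1 and 55074 ± 11802 at day 3 (SD, n = 9 each), a difference of -20400.2 counts (exact two-sided permutation p = 5.76e-04). The gene count total moved the other way, from 1021946 to 1445207 counts (exact two-sided permutation p = 0.00173, n = 9 each). Over all 18 samples the 2 sums had a Pearson correlation of -0.842 (permutation p = 3.00e-05, adjusted p = 1.20e-04 over 4 relations) and a Spearman correlation of -0.822 (permutation p = 4.00e-05, adjusted p = 1.60e-04). Without the 2 samples farthest from the median gene total, r was -0.782 (permutation p = 3.30e-04).

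More RNA counted in a lane may lower its positive-control count. Within day 3 the correlation was -0.815 (exact permutation p = 0.00288, adjusted p = 0.00384, Spearman -0.833, n = 9). Within day 1 it was -0.377 (exact permutation p = 0.316, adjusted p = 0.316, Spearman -0.267, n = 9), which does not settle it. The day itself is the other explanation: with the gene total in the model its term on the log2 positive-control sum went from -0.48 to -0.21 (permutation p = 0.106). Day and gene total cannot be told apart here, since the gene total differs between the days and each day holds 9 samples.

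At day 3 the likelihood ratio model with a background term called 2 probes, both higher with iECM, and the quasi-likelihood test called 0. This model, fitted to 4 hearts against 5, may give too many small p-values. In counts simulated with no change, 0.101 of its unadjusted p-values were under 0.05, and 18 of 20 simulations gave at least 1 call, against 4 of 50 for the quasi-likelihood test. The form of the test alone does not show this: edgeR's likelihood ratio test, fitted to all 18 samples, also called 0 probes at day 3, and in simulation 0.0471 of its unadjusted p-values were under 0.05, with a call in 10 of 50 simulations. The model also differs in its background term, its scaling and its dispersions, and which of these matters was not tested. Chance could not be excluded either: 32 of 100 splits of the 9 day 3 hearts gave as many calls. The median other split gave 0 calls and the highest gave 104. The simulated counts thus gave calls more often than the regrouped real counts. At day 1 the model called 0 of 374 probes, and 10 had an unadjusted p under 0.05. How far the simulation carries over to the real counts was not tested. The agent stays open as an explanation of these 2 calls.

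Other splits of the samples were counted for the remaining results, each number including the real split. For the 3 counts of 0 called probes this decides nothing, since 100 of 100 splits must give at least 0. The highest other split gave 9 calls at day 1, 20 at day 3 and 5 for the interaction, and the median other split gave 0 in each case. At day 1, 98 of 100 splits gave at least the 3 probes at an unadjusted p under 0.05, with a median of 10 and a highest of 104 among the others. At day 3, 42 of 100 gave at least the 11 probes at an unadjusted p under 0.05, with a median of 7 and a highest of 127 among the others. For the correlation of the effects on the 2 days, 72 of 100 regroupings lay as far from 0 as -0.123, the farthest other at 0.536. Chance cannot be excluded for these numbers of probes at an unadjusted p under 0.05 or for the correlation. What sets the highest splits apart was not tested.

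For day 3 against day 1 in control hearts, 1 of 35 splits, the real one, gave 169 called probes, and the highest other gave 5. In iECM hearts 1 of 100 splits, the real one, gave 154, and the highest other gave 137. Chance is an unlikely explanation for both, but is not excluded. In control hearts 1 of 35 is the smallest share that the splits can give, and in iECM hearts another split came close. How many hearts that split kept in their real group was not examined, so its count alone does not decide. Among 32 tests of a sample far from its group in depth, control counts and principal components, 0 were past the limit.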

How the results depend on the processing

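The likelihood ratio tests, positive-control scaling, the covariate, the background filter, the pair of left-out samples and unscaled limma were chosen after seeing the data. No paired analysis was possible because the labels give no replicate numbers. The day 1 count of 0 was 0 under each of 20 alternatives and each sample left out. The day 3 count of 0 became 2 under the likelihood ratio model with a background term. The interaction count of 0 became 3 with the within-group axis as a covariate. That covariate also raised the number of small day 3 p-values in other splits. Such splits were not run for the interaction, so the cause of its 3 calls was not tested. The count in control hearts ranged from 156 to 251, and from 121 to 193 with 1 sample left out. The count of 154 in iECM hearts ranged from 143 to 262, from 131 to 193 with 1 sample left out, and was 239 with sample quality weights and 262 with positive-control scaling. Probes called the same way in both agents numbered 119, from 100 to 162 with 1 sample left out, 184 with quality weights and 226 with positive-control scaling. With positive-control scaling 249 probes rose and 2 fell in control hearts, and 259 rose and 3 fell in iECM hearts. Its shared calls are therefore almost all rises, and they depend on that scaling. The cause of the higher numbers with quality weights was not tested. The correlation of -0.123 between the effects on the 2 days was 0.207 without the 2 samples farthest out on the within-group axis. These were day 3 iECM replicate 1 and day 1 control replicate 1. With 1 sample left out the correlation ranged from -0.361 without day 1 control replicate 2 to 0.359 without day 1 control replicate 1. Probes with an interval inside a 2-fold change ranged from 278 to 351 at day 1 and from 310 to 350 at day 3 in the alternatives that tested 371 probes. They were 271 and 263 of the 285 tested with the lowest probes left out, and 279 and 271 of the 294 with a mean above background in every group. Unscaled limma moved the median of all probes by 0.70 in control hearts and 0.39 in iECM hearts, and gave 197 rising and 3 falling probes in control hearts and 135 and 14 in iECM hearts. Row 273 lost its call in control hearts there (-1.03, limma adjusted p = 0.101, against 1.04e-04 as the smallest over its alternatives). The other 7 effects of the named rows kept their direction and their call in all alternatives run. Scaling on named housekeeping genes, list tests and, for the interaction, a fit of only the groups compared were not run. With 20 changed probes, 32.5% of 1.5-fold changes were recovered in simulation with probes drawn independently. Single effects of that size at day 3 were thus mostly not detectable in such counts.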

Other observations

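The test with the within-group axis as a covariate was chosen only after its result was seen, and the removal of other pairs and of single genes after that of Il1b and Il6.

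In the authors' deposited gene ontology table for day 3, response to mechanical stimulus came first and held 10 of the 23 genes: Cd36, Cxcl10, Il1b, Il6, Junb, Nos2, Pdgfb, Slc2a1, Thbs1 and Timp3 (adjusted p = 5.67e-09). Nitric oxide biosynthetic process held Cd36, Il1b, Il6, Mmp8 and Nos2 in the authors' deposited table (adjusted p = 1.39e-05). Regulation of vasculature development held Cd36, Crhr2, Cxcl10, Il1b, Lrg1, Pdgfb and Thbs1 in the authors' deposited table (adjusted p = 2.07e-05). The authors' deposited fold changes go both ways within these terms, each of which holds Cd36 at 0.45 and Il1b at -0.38. The authors' deposited table used 17962 background genes, more than the 374 that could have been listed.

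Il1b and Il6 recur through the authors' deposited tables, with at least 1 of them in 31 of 38 KEGG pathways and in 460 of 707 gene ontology terms. A few cytokine genes shared between pathways may account for much of the KEGG list. With Il1b and Il6 taken out of the input, the background and the pathways, 3 of the 38 pathways kept an adjusted p under 0.05 over the 102 tested. They were adipocytokine signaling (Cd36, Cpt1a and Slc2a1), insulin resistance and TNF signaling, and 6 pathways had no gene left. Another 6 of the lost pathways never held Il1b or Il6, and fell only through the adjustment, to which the other pathways contribute. The adjustment still counted all 102 pathways, including those with no gene left. Malaria, IL-17 signaling, PPAR signaling and others shared a hypergeometric adjusted p of 0.0897, so the number kept depends strongly on the threshold. The 78 pairs of listed genes without Il1b and Il6, removed in the same way, kept between 31 and 38 pathways. Without Il6 alone 7 pathways were kept, and without Il1b alone 16, against 32 to 38 without any other single gene. These numbers largely restate membership, since Il6 is in 29 listed pathways, Il1b in 25 and no other gene in more than 10. With another gene removed as well, 4 to 9 were kept without Il6 and 6 to 27 without Il1b. A second removal can thus raise the number kept, as from 16 without Il1b to 27 without Il1b and Junb. The number kept is therefore not a measure of the weight of a gene. Whether Il1b and Il6 differed between the agents is a separate matter, since their q-values in the authors' deposited table were 0.182 and 0.531.

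The leading axis of variation within groups held 39.4% of the variance around the group means. With it as a covariate, 56 probes at day 3 had an unadjusted p under 0.05, against 11 without it. Of 100 splits of the day 3 hearts with the axis taken anew in each, 44 gave as many, so chance cannot be excluded. The median other split gave 41 and the highest 173, against a median of 7 without the covariate. The covariate thus goes with more small p-values in other groupings of these hearts too.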
